A study of Homo sapiens with 9 samples.

How the data were processed

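Poly(A)-selected RNA from 9 cultures of cells labelled MCF-7 was sequenced as paired-end Illumina reads, with 3 independent biological replicates in each of the Control, CLUSTER and MARRS groups. The authors deposited a table of read counts, without normalization, with 1 column per library and no column of other samples. Per the submitters' processing notes, the reads were handled with CASAVA, HISAT2, StringTie, DESeq2 and GATK on GRCh38, and neither the role nor the version of each tool is given. The tool that made the counts and its use of strand are not stated, so the scale of the counts relative to sequenced fragments is unknown. The table held 23427 features, of which 20463 carried an Ensembl gene identifier and 2964 carried an MSTRG identifier, the form StringTie gives to assembled transcripts. Symbols stood beside 19451 of the Ensembl identifiers. Of the 14855 Ensembl features tested, 14749 (99.3%) were found in GENCODE 29, which gave positions, lengths and GC content on GRCh38.

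Total counts per library ranged from 157265083 to 190445581. That depth makes counting error small beside the spread between cultures, and it was not used as a measure of precision. All tests rest on the spread between libraries.

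Counts were fitted in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood, with all 9 libraries in 1 fit and no covariate, TMM factors and the default low-count filter by group (filterByExpr), which left 16933 features, 2078 of them MSTRG features. The contrasts were CLUSTER versus Control, MARRS versus Control and MARRS versus CLUSTER. A gene was called at an adjusted p under 0.05, with Benjamini-Hochberg adjustment over all features of a comparison, and a size threshold of 1 in log2 fold change was counted beside it. Adjusted p values of single genes in the text come from this edgeR test unless another tool is named. Expression is given as CPM, the count per 1e6 counts of the TMM-scaled library size, as mean and SD over the 3 libraries of a group. Fold changes carry the SE that the fit implies, the log2 fold change over the square root of its F statistic.

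The groups, tests, named genes, gene lists and most of the other settings were fixed before the data were examined. The 25 lists, from textbook knowledge, were RNA editing enzymes and cofactors, known ADAR substrates, double-stranded RNA sensing, interferon-stimulated genes, NF-kB and inflammatory genes, integrated stress response, endoplasmic reticulum unfolded protein response, p53 targets, estrogen response, luminal breast epithelial identity, basal and mesenchymal genes, fibroblast markers, blood cell markers, neural and embryonic kidney line markers, G1/S cell cycle, G2/M cell cycle, heat shock response, cholesterol and fatty acid synthesis, lysosome, hypoxia and glycolysis, NRF2 oxidative stress, immediate early genes, mitochondrially encoded genes, cytosolic ribosomal proteins, and transcripts without a poly(A) tail. Of their 620 members, 615 were found in the table. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count of 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment ran over the 75 tests of 25 lists in 3 comparisons. Camera sets the genes of a list against all other genes, whereas fry asks whether the genes of a list move, on balance, in 1 direction. Beside the members called over all features, members were counted after the p values were adjusted over the list alone.

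Named genes were ADAR, ADARB1 and ADARB2, the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between the 3 and 3 libraries, and up to 3 called members with the smallest p of each list. Where fewer than 5 genes were called, the 3 rises and 3 falls with the smallest unadjusted p among genes of at least 5 CPM were added as values. Genes named outside this rule are marked as chosen after their values were seen.

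The overlap of both comparisons with Control was set against the product of their shares and against 20 simulations of unchanged groups that shared their controls. The 3 Control libraries were too few to be divided between the comparisons. Library structure was described by principal components of log2 CPM, Pearson correlations across genes, and a chi-square statistic per gene for each pair of libraries, over features with at least 20 counts in the pair. The test was also run on simulated data of the same design with 50 genes at each of 4 effect sizes. In CLUSTER versus Control it recovered 6% of the genes changed 1.25-fold, 24% at 1.5-fold, 82% at 2-fold and 98% at 4-fold, and called 4 of 16397 unchanged features. The changed genes were drawn from features with a mean of at least 5 CPM and were few beside the calls in the data. These shares therefore do not measure the sensitivity of the comparisons reported below.

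The other settings chosen then were DESeq2 1.42.0, limma-voom, DESeq2 size factors or upper-quartile factors in place of TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, only the 6 libraries of a comparison, the replicate number as a block, and each compared library left out in turn. Settings added after seeing the data were each library of the uncompared group left out, the MSTRG features left out, and offsets per library from splines on gene length and GC content. Other splits of the 6 libraries of each comparison into 3 and 3 were also counted. Sequence variants and editing sites were not analysed, since the deposited table holds counts only.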

Results

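RNA sequencing of poly(A)-selected RNA gave read counts for 9 cultures labelled MCF-7, a human breast cancer line described as luminal and estrogen receptor positive. The cultures formed a Control, a CLUSTER and a MARRS group of 3 libraries each. The series concerns RNA editing by ADAR1 that is recruited in the cell through aptamers, RNA elements that bind a chosen protein. ADAR1, the product of ADAR, converts adenosine to inosine in double-stranded RNA. In the field CLUSTER is the name of a guide RNA design that recruits the cell's own ADAR, but the labels define neither arm nor what the Control cultures received. Total counts per library ranged from 157265083 to 190445581. Among genes chosen here after their values were seen, 3 luminal genes were near zero across all 9 libraries, with ESR1, the estrogen receptor, at 0.172 ± 0.119 CPM (SD, n = 9), the transcription factor GATA3 at 0.436 ± 0.0981 CPM and the adhesion gene CDH1 at 0.0673 ± 0.0479 CPM. The luminal keratin KRT8 stood at 984 ± 231 CPM. VIM, also chosen after its values were seen, encodes the mesenchymal filament protein vimentin and stood at 1597 ± 126 CPM.

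The first principal component of log2 CPM held 22.8% of the variance, and CLUSTER libraries had scores of 39.3 to 90.0 on it. MARRS replicates 1 and 3 scored -29.9 and -35.0, whereas MARRS replicate 2 scored 22.2. Across genes, which are not independent replicates, MARRS replicate 2 correlated with CLUSTER replicates 1, 2 and 3 at r = 0.954, 0.9415 and 0.947, with MARRS replicates 1 and 3 at r = 0.944 and 0.940, and with the Control libraries at r = 0.944 to 0.947, so that r did not place it. The chi-square per gene was 44.2 between MARRS replicates 1 and 3 and 445 between replicates 1 and 2. Between MARRS replicate 2 and the CLUSTER libraries it was 101 to 189, near the 126 to 140 within CLUSTER. MARRS values below use all 3 libraries, with the value without replicate 2, a leave-out fit singled out after seeing the data, beside many of them. The p values and calls of that fit do not take in the distance of replicate 2 from MARRS replicates 1 and 3.

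**Figure D1:**
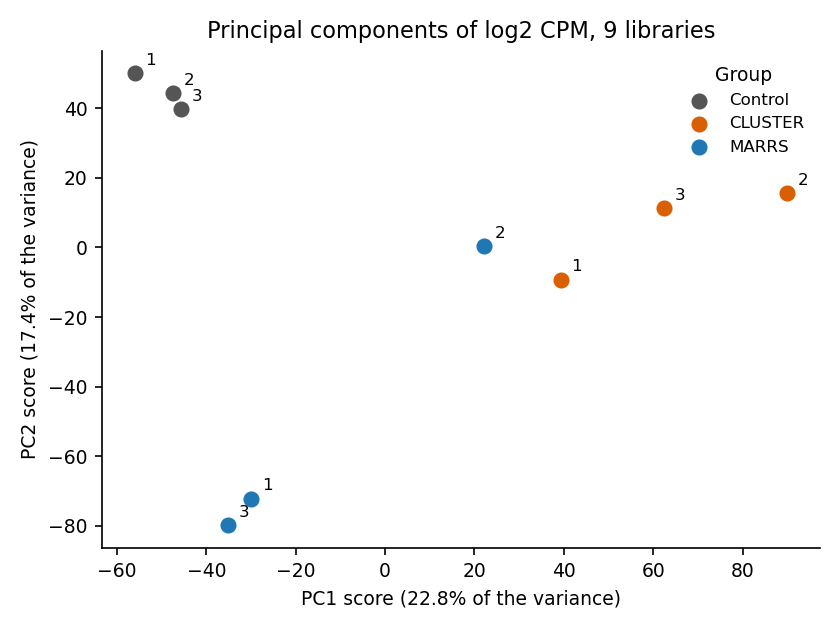
Principal component scores of log2 CPM for the 9 libraries, PC1 (22.8% of the variance) on the horizontal and PC2 (17.4%) on the vertical axis, coloured by group, with the replicate number beside each point. MARRS replicate 2 has a PC1 score of 22.2, while MARRS replicates 1 and 3 have scores of -29.9 and -35.0.

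ADAR (ENSG00000160710, chromosome 1, 154582057 to 154628013 on GRCh38) had 499, 502 and 549.6 CPM in the Control libraries, with a mean of 517 ± 28.3 CPM (SD, n = 3). The CLUSTER libraries had 877, 942 and 880.0 CPM, a mean of 899.8 ± 36.8 CPM (n = 3), and the rise was 1.74-fold (log2 fold change 0.80, SE 0.22, adjusted p = 0.0278). MARRS replicates 1, 2 and 3 had 506, 915 and 487 CPM, so that replicate 2 stood at the CLUSTER level, and the log2 fold change against Control was 0.30 (SE 0.22, adjusted p = 0.369). Without MARRS replicate 2, ADAR in MARRS differed from Control by -0.07 (adjusted p = 0.402) and from CLUSTER by -0.87 (adjusted p = 0.000152). With all libraries the difference between MARRS and CLUSTER was -0.50 (adjusted p = 0.194). The ADAR call in CLUSTER ended when any Control or CLUSTER library was left out, with adjusted p of 0.0584 to 0.0912 and log2 fold changes of 0.77 to 0.84. Leaving MARRS replicate 2 out of the fit instead gave this contrast a log2 fold change of 0.80 with a smaller SE of 0.051 (adjusted p = 6.32e-05). ADARB1, the gene of the second catalytic editing enzyme, had 91.7 ± 5.34 CPM in Control, 88.0 ± 3.85 in CLUSTER and 96.6 ± 6.54 in MARRS, with adjusted p of 0.579 and 0.479 against Control. ADARB2, whose protein has no known editing activity, was too low to test, at no more than 0.0446 CPM in any library.

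**Figure D2:**
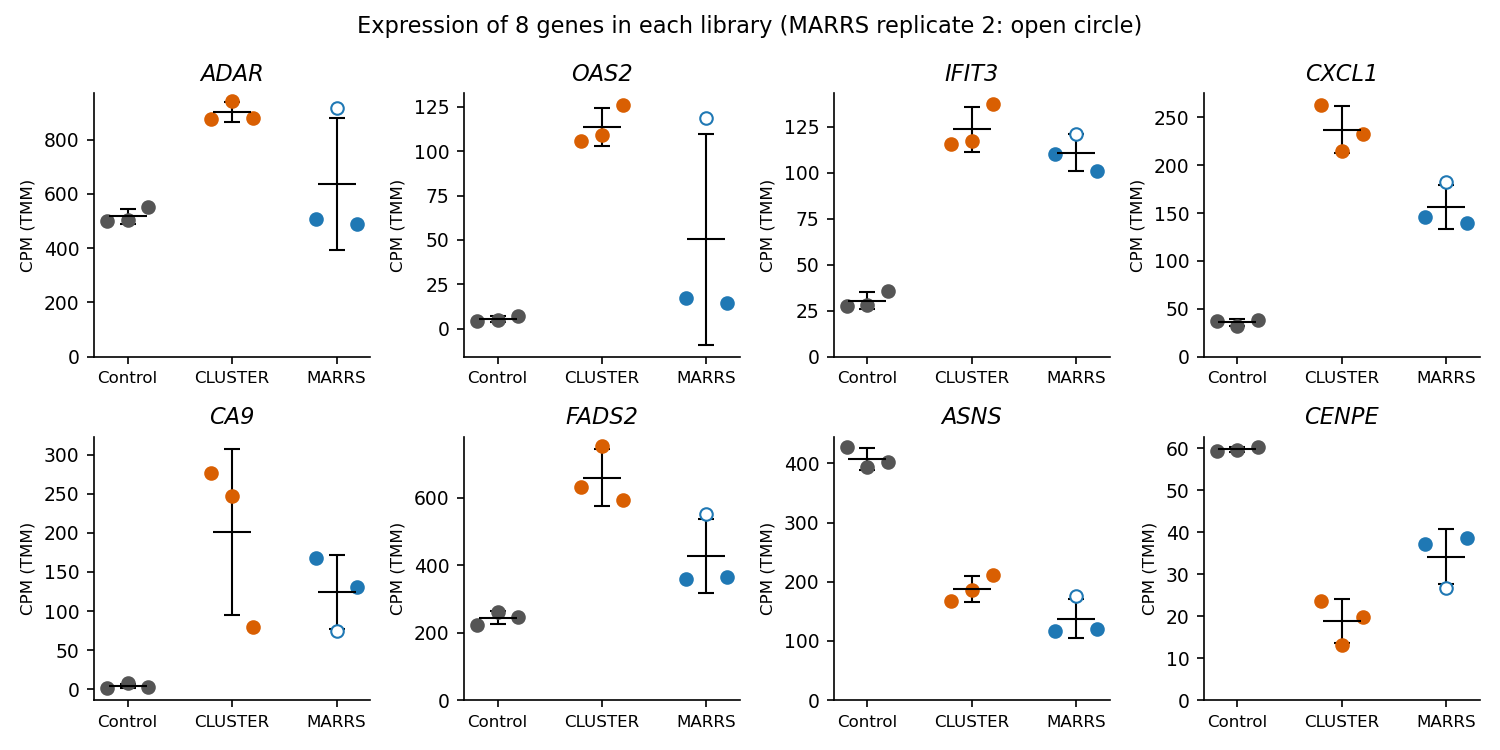
CPM on TMM-scaled library sizes of 8 genes in each of the 9 libraries, grouped as Control, CLUSTER and MARRS, with black bars for the mean ± SD of 3 libraries and an open circle for MARRS replicate 2. In the ADAR panel that library stands at 915 CPM and the other MARRS libraries at 506 and 487 CPM.

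The comparison of CLUSTER with Control asked how the transcriptome differed in that arm. Camera called the lists of interferon-stimulated genes (42 of 50 higher), hypoxia and glycolysis (28 of 28), NF-kB and inflammatory genes (15 of 25) and cholesterol and fatty acid synthesis (19 of 27) upward in CLUSTER. It called the integrated stress response (20 of 29 lower, 2 higher) and G2/M lists (15 of 27 lower, 1 higher) downward, and all 6 had an adjusted p = 0.579 with an estimated correlation. TRIM22 (ENSG00000132274, chromosome 11, 5689689 to 5737089), an interferon-induced antiviral gene, rose 49.6-fold, from 0.483 ± 0.214 CPM to 24.1 ± 1.05 CPM (SD, n = 3 each). CA9 (ENSG00000107159, chromosome 9, 35673856 to 35681159), a carbonic anhydrase induced by HIF1, rose 48.2-fold, from 4.17 ± 2.90 to 201 ± 106 CPM. BMF (ENSG00000104081, chromosome 15, 40087890 to 40108892), a pro-apoptotic member of the BCL2 family, had the largest fall among the named genes, from 11.7 ± 1.81 to 1.72 ± 0.729 CPM.

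Of 50 interferon-stimulated genes tested, 42 were higher in CLUSTER and 0 lower, 36 of them by 2-fold or more, and 46 were higher when adjusted over the list alone. The median log2 fold change of the list was 1.64, with a camera adjusted p of 3.08e-17 and an adjusted p of 0.579 with an estimated correlation. IFIT3, an interferon-induced antiviral gene, rose 4.06-fold, from 30.4 ± 4.69 to 123 ± 12.1 CPM. OASL, a relative of the oligoadenylate synthetases, rose 4.09-fold and IFI44 3.52-fold. MX2, a dynamin-like antiviral gene, went from 7.25 ± 2.53 to 116 ± 12.5 CPM. Among 19 genes of double-stranded RNA sensing, 10 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.55 and a camera adjusted p of 0.0116, or 0.579 as the adjusted p with an estimated correlation. OAS2, an oligoadenylate synthetase that is switched on by double-stranded RNA, rose from 5.49 ± 1.52 to 114 ± 10.7 CPM (log2 fold change 4.37, SE 0.83, adjusted p = 0.00602). DHX58, a RIG-I-like receptor, rose 4.63-fold, while MAVS, the adaptor of these receptors, and TBK1, the kinase downstream of it, fell to 0.660 and 0.669 of the Control level.

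All 28 genes of the hypoxia and glycolysis list were higher in CLUSTER, over all features and adjusted over the list alone, 19 of them by 2-fold or more. Their median log2 fold change was 1.46 (camera adjusted p = 3.89e-17, adjusted p = 0.579 with an estimated correlation). ADM, the vasodilator peptide adrenomedullin, rose 8.14-fold, from 13.0 ± 0.431 to 106 ± 17.6 CPM. PFKFB4, which makes an activator of glycolysis, rose 4.66-fold, and SLC2A1, the glucose transporter GLUT1, went from 197 ± 7.38 to 647 ± 97.8 CPM. ANGPTL4, a lipoprotein lipase inhibitor of the same list, rose 30.3-fold. The mitochondrial share of counts was 2.23% to 3.15% in CLUSTER and 1.77% to 2.03% in Control. The list of 13 mitochondrially encoded genes had 2 higher members and 0 when adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.0138, adjusted p = 0.691 with an estimated correlation). That list call ended without CLUSTER replicate 3 (adjusted p = 0.0629), whereas leaving MARRS replicate 2 out of the fit gave 13 higher of 13 (camera adjusted p = 0.000182, adjusted p = 0.494 with an estimated correlation).

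Of 25 NF-kB and inflammatory genes, 15 were higher and 0 lower, and 22 were higher adjusted over the list alone. The median was 1.39 (camera adjusted p = 5.25e-09, adjusted p = 0.579 with an estimated correlation). CXCL1, a chemokine that attracts neutrophils, rose 6.62-fold, from 35.7 ± 3.30 to 237 ± 24.6 CPM. The cytokine IL6 rose 4.77-fold, IL1B rose 12.2-fold from a low level of 0.377 ± 0.146 CPM, and the chemokine CCL20 rose 21.3-fold. Among 27 genes of cholesterol and fatty acid synthesis, 19 were higher and 0 lower (25 adjusted over the list alone), with a median of 1.08 (camera adjusted p = 4.47e-08, adjusted p = 0.579 with an estimated correlation). FADS2 and FADS1, fatty acid desaturases, rose 2.70-fold and 2.09-fold, and SC5D, an enzyme late in cholesterol synthesis, rose 1.60-fold. Of 18 genes of the endoplasmic reticulum unfolded protein response, 9 were higher and 2 lower (13 and 2 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.000166, adjusted p = 0.579 with an estimated correlation). The chaperone HSPA5 rose from 787 ± 13.8 to 1421 ± 176 CPM, and CALR and MANF rose 1.78-fold and 1.85-fold.

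In the integrated stress response list, 20 of 29 genes were lower in CLUSTER and 2 higher, with 20 and 3 adjusted over the list alone. The median was -0.85 (camera adjusted p = 1.55e-05, adjusted p = 0.579 with an estimated correlation). PSPH, an enzyme of serine synthesis, fell to 0.378 of the Control level, from 84.6 ± 2.56 to 31.9 ± 3.66 CPM. GARS1, the glycyl-tRNA synthetase, and MTHFD2, a mitochondrial enzyme of folate metabolism, fell to 0.472 and 0.489 of it. Outside the list, CTH, which makes cysteine from cystathionine, fell from 29.7 ± 2.19 to 8.35 ± 0.627 CPM, and NIBAN1, a stress-responsive gene, from 147 ± 9.16 to 44.3 ± 2.92 CPM. Of 27 G2/M genes, 15 were lower and 1 higher (16 and 1 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 2.23e-05, adjusted p = 0.579 with an estimated correlation). CENPE, a kinesin of the mitotic spindle, fell from 59.7 ± 0.511 to 18.8 ± 5.32 CPM. HMMR, a spindle assembly gene, fell to 0.546 of the Control level and CCNB2, a mitotic cyclin, to 0.728. In the NRF2 list, 4 of 22 genes were lower and 0 higher, also adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0152, adjusted p = 0.630 with an estimated correlation, and 0.208 by camera without CLUSTER replicate 1). SLC7A11, the cystine transporter, fell to 0.425 of the Control level and GCLM, a subunit of the enzyme that starts glutathione synthesis, to 0.597.

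Of 22 lysosome genes, 9 were higher and 1 lower, also adjusted over the list alone (median 0.13, camera adjusted p = 0.0138, adjusted p = 0.579 with an estimated correlation). The lysosomal sialidase NEU1 rose 1.73-fold and the membrane protein LAMP2 fell to 0.762 of the Control level. Of 24 immediate early genes, 7 were higher and 1 lower, also adjusted over the list alone (median 0.38, camera adjusted p = 0.0170, adjusted p = 0.691 with an estimated correlation). The transcription factor JUN rose 2.88-fold and CCN1, a secreted matrix protein, 3.44-fold. This list call ended without Control replicate 2 (adjusted p = 0.0715), CLUSTER replicate 1 or CLUSTER replicate 3.

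The camera test called none of the other 13 lists. RNA editing enzymes and cofactors had 4 higher and 1 lower of 16 (adjusted p = 0.753), with a median of -0.03 against an upward test statistic. Of this list, ILF2 rose 1.20-fold and ILF3, the 1 lower member, fell to 0.839 of the Control level. Known ADAR substrates had 5 higher and 1 lower of 17 (adjusted p = 0.347), among them FLNB, an actin cross-linker, at 1.37-fold. Fry did call this list upward (adjusted p = 0.0225). Basal and mesenchymal genes had 4 higher of 23 (adjusted p = 0.170), with the keratin KRT17 going from 1045 ± 37.2 to 3159 ± 71.6 CPM. Luminal identity genes had 5 higher and 1 lower of 19 (adjusted p = 0.175), with the keratin KRT8 up 1.74-fold and the androgen receptor AR at 0.310 of the Control level. Blood cell markers had 3 higher of 7 (adjusted p = 0.0610), of which CD68, also a lysosomal protein of many cell types, went from 7.85 ± 0.821 to 15.8 ± 0.217 CPM. Fibroblast markers had 1 higher of 11 (adjusted p = 0.847), with a median of 0.11 and a mean of -0.12, and neural and embryonic kidney line markers had 2 higher of 5 (adjusted p = 0.263). Estrogen response genes had 6 higher and 2 lower of 24 (adjusted p = 0.263), p53 targets 7 and 4 of 24 (adjusted p = 0.948, median -0.10 against an upward statistic) and G1/S genes 5 and 1 of 26 (adjusted p = 0.208). Heat shock genes had 1 higher and 1 lower of 18 (adjusted p = 0.406), cytosolic ribosomal proteins 2 and 3 of 61 (adjusted p = 0.555) and transcripts without a poly(A) tail 2 higher of 14 (adjusted p = 0.0788).

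Over all features, 5064 of 16933 were called between CLUSTER and Control, 2556 higher and 2508 lower, and 1019 of them had a change of 2-fold or more (692 higher, 327 lower). Without Control replicate 1, 2 or 3 the calls were 3169, 3282 and 3143. No list call held with an estimated correlation, and 8 of the 12 were also called by fry. Fry called 4 further lists, all upward. They were known ADAR substrates, luminal identity genes (fry adjusted p = 0.0120), blood cell markers (0.0157) and neural and embryonic kidney line markers (0.0165). In the fit without MARRS replicate 2, fry called 20 of the 25 lists. MARRS replicate 2 is in neither group, but its removal from the fit raised the counts of higher genes to 24 for the NF-kB list, 12 for immediate early genes, 10 for the estrogen list, 8 each for luminal and G1/S genes, 7 for basal and mesenchymal genes and 6 for heat shock genes, and gave 7 lower NRF2 genes. Cytosolic ribosomal proteins then had 9 higher and 7 lower, p53 targets 8 and 6, and 4 estrogen genes were lower and 4 integrated stress response genes higher. It also added a call of transcripts without a poly(A) tail (5 higher of 14, camera adjusted p = 0.0272, adjusted p = 0.377 with an estimated correlation).

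The comparison of MARRS with Control asked the same of the other arm. Camera called the hypoxia and glycolysis list (21 of 28 higher) and interferon-stimulated genes (25 of 50 higher) upward, and the integrated stress response (17 of 29 lower, 3 higher) and cytosolic ribosomal proteins (21 of 61 lower) downward, each with an adjusted p = 0.579 with an estimated correlation. CA9 rose 29.8-fold, from 4.17 ± 2.90 to 124 ± 47.1 CPM (SD, n = 3 each), and DKK1 (ENSG00000107984, chromosome 10, 52314296 to 52318042), a secreted Wnt inhibitor, rose 17.6-fold to 12.9 ± 1.30 CPM. ASNS (ENSG00000070669, chromosome 7, 97852118 to 97872542), the asparagine synthetase, fell from 408 ± 18.4 to 138 ± 33.1 CPM. RPL5, a protein of the large ribosomal subunit, fell from 1103 ± 9.04 to 809.7 ± 8.88 CPM.

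Of the 28 hypoxia and glycolysis genes, 21 were higher in MARRS and 0 lower (22 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 8.74e-11, adjusted p = 0.579 with an estimated correlation). ADM rose 5.01-fold, PFKFB4 3.41-fold and P4HA1, a collagen prolyl hydroxylase, 2.21-fold. Of 50 interferon-stimulated genes, 25 were higher and 0 lower (32 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 1.53e-09, adjusted p = 0.579 with an estimated correlation). IFIT3 rose 3.64-fold to 111 ± 10.04 CPM, OASL 3.53-fold and IFI44 3.56-fold. TRIM22 and OAS2 rested partly on MARRS replicate 2, since their log2 fold changes of 4.18 and 3.19 became 1.97 and 1.54 without it. Their calls also ended when any Control library was left out, with adjusted p of up to 0.0875 and 0.0887. The interferon list had 30 higher and 5 lower genes and a median of 0.48 without MARRS replicate 2. Of 19 double-stranded RNA sensing genes, 6 were higher and 3 lower (camera adjusted p = 0.435) and the median was 0.13, or -0.03 without MARRS replicate 2, with DHX58 up 4.09-fold and MAVS at 0.725 of the Control level.

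In the integrated stress response list, 17 of 29 genes were lower in MARRS and 3 higher (19 and 5 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 2.57e-07, adjusted p = 0.579 with an estimated correlation). PSPH fell to 0.372, GARS1 to 0.461 and MTHFD2 to 0.466 of the Control level. Outside the list, ADM2, a peptide related to adrenomedullin, fell from 19.0 ± 1.79 to 3.58 ± 0.473 CPM, and UNC5B, a netrin receptor, from 11.1 ± 1.16 to 2.09 ± 0.568 CPM. Of 61 cytosolic ribosomal protein genes, 21 were lower and 0 higher (36 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 2.05e-09, adjusted p = 0.579 with an estimated correlation). RPL7 and RPS6 fell to 0.783 and 0.763 of the Control level. The mitochondrial share of counts was 1.37%, 2.84% and 1.27% in MARRS replicates 1, 2 and 3, and without replicate 2 the ribosomal list had 54 lower genes and a median of -0.35. Of 22 NRF2 genes, 8 were lower and 0 higher (11 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.00106, adjusted p = 0.579 with an estimated correlation). With MARRS replicate 2 left out, 13 NRF2 genes were lower and 2 higher (adjusted p = 0.571 with an estimated correlation). GCLM and GCLC, both subunits of the enzyme that starts glutathione synthesis, fell to 0.568 and 0.608 of the Control level.

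Of 25 NF-kB and inflammatory genes, 6 were higher in MARRS and 0 lower, also adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.0106, adjusted p = 0.736 with an estimated correlation). CXCL1 rose 4.37-fold, IL6 4.28-fold and the chemokine CXCL8 5.81-fold. Without MARRS replicate 2 the list had 7 higher and 9 lower genes and a median of -0.11 (camera adjusted p = 0.769). The cholesterol list had 2 higher of 27, also adjusted over the list alone, and a median of 0.44 (camera adjusted p = 0.0208, adjusted p = 0.765 with an estimated correlation), and SC5D rose 1.41-fold. Its median was 0.02 without MARRS replicate 2 (camera adjusted p = 0.632), with a downward statistic. Of 18 unfolded protein response genes, 9 were higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00111, adjusted p = 0.579 with an estimated correlation), and CALR and HSPA5 rose 1.64-fold and 1.61-fold.

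Of 11 fibroblast markers, 5 were higher in MARRS and 0 lower (6 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.00667, adjusted p = 0.579 with an estimated correlation), and 8 were higher without MARRS replicate 2. COL1A1, a fibrillar collagen gene, rose from 71.6 ± 5.67 to 193 ± 81.7 CPM, with a log2 fold change of 1.43, or 1.74 without MARRS replicate 2, and its call ended without Control replicate 1 (adjusted p = 0.0587) or Control replicate 3. Of 26 G1/S genes, 8 were lower and 3 higher (11 and 3 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.0247, adjusted p = 0.752 with an estimated correlation). E2F2, a transcription factor of S-phase entry, fell to 0.563 of the Control level. The G1/S call ended without MARRS replicate 1 (adjusted p = 0.0847) or MARRS replicate 3, and without MARRS replicate 2 there were 16 lower and 2 higher genes (camera adjusted p = 0.000852, adjusted p = 0.547 with an estimated correlation). Of 24 immediate early genes, 7 were higher and 0 lower, also adjusted over the list alone (median 0.29, camera adjusted p = 0.0383, adjusted p = 0.736 with an estimated correlation), with CCN1 up 4.62-fold. The immediate early call ended without MARRS replicate 2 (6 higher and 6 lower, adjusted p = 0.891), Control replicate 2 or Control replicate 3. Blood cell markers (1 higher of 7, also adjusted over the list alone, camera adjusted p = 0.0247) and basal and mesenchymal genes (6 higher of 23, 7 adjusted over the list alone, camera adjusted p = 0.0472) were called as well, each with an adjusted p of 0.579 with an estimated correlation. The blood call ended without MARRS replicate 2 (adjusted p = 0.0651), and the basal call without any of 5 libraries (adjusted p of up to 0.0927), while 12 basal genes were higher and 4 lower without MARRS replicate 2. KRT17 rose 2.41-fold to 2515 ± 388 CPM. The G2/M list was not called (3 lower of 27, camera adjusted p = 0.662), with a median of 0.02 against a downward statistic, and had 8 higher and 3 lower genes and a median of 0.14 without MARRS replicate 2 (camera adjusted p = 0.117).

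Heat shock genes had 1 higher and 1 lower of 18 with all libraries (camera adjusted p = 0.244). In the fit without MARRS replicate 2 they had 13 lower and 2 higher and a median of -0.37 (camera adjusted p = 0.000902, adjusted p = 0.377 with an estimated correlation). Mitochondrially encoded genes went from 0 called of 13 and a median of 0.02 (camera adjusted p = 0.847) to 9 lower and a median of -0.54 in that fit (camera adjusted p = 0.00609, adjusted p = 0.568 with an estimated correlation).

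Over all features, 4100 of 16933 were called between MARRS and Control, 2159 higher and 1941 lower, and 704 had a change of 2-fold or more (521 higher, 183 lower). Without MARRS replicate 2 the calls were 6421, without MARRS replicate 1 or 3 they were 2194 and 2245, and without Control replicate 1, 2 or 3 they were 1968, 2101 and 1886. No list call held with an estimated correlation, and 7 of the 13 were also called by fry. Fry called 2 further lists upward, known ADAR substrates (fry adjusted p = 0.0444) and neural and embryonic kidney line markers (0.00957). Camera had adjusted p of 0.411 and 0.395 for them. In the fit without MARRS replicate 2, fry called 14 of the 25 lists.

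**Figure D3:**
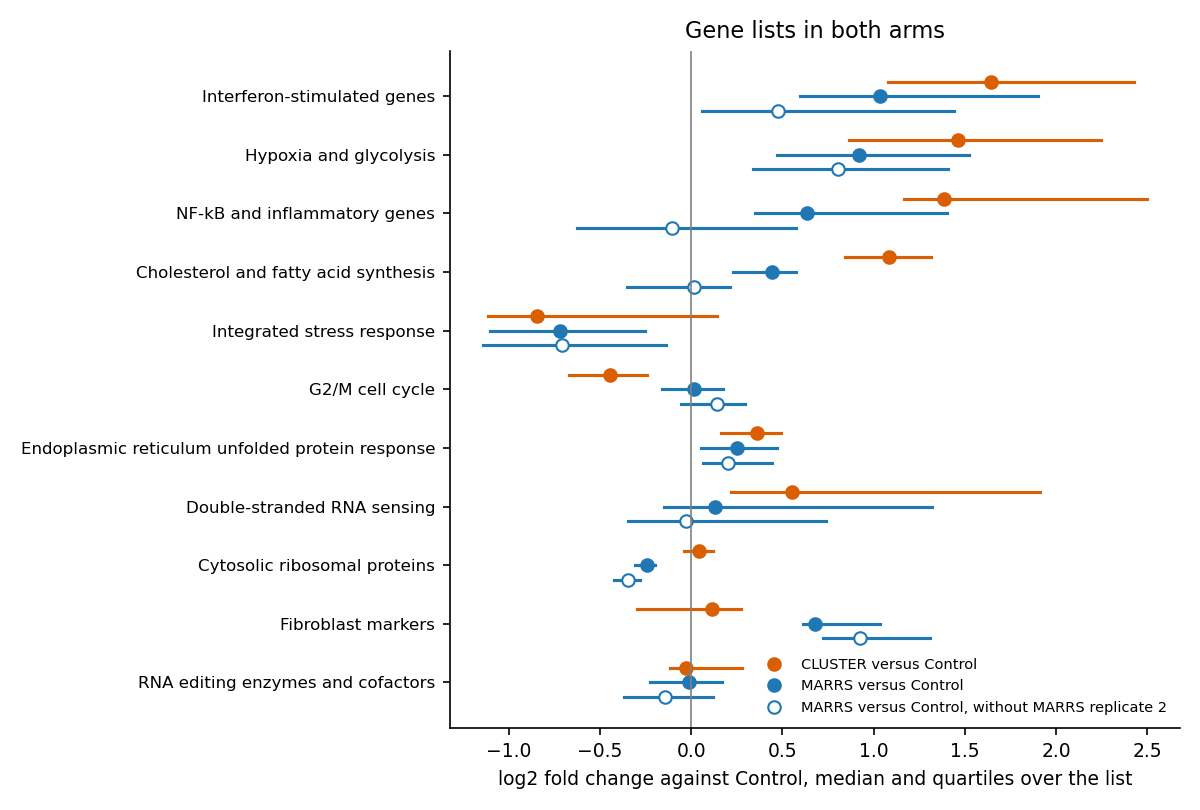
Median log2 fold change against Control, with bars from the lower to the upper quartile over the tested genes, for 11 gene lists in CLUSTER (orange), MARRS (blue) and MARRS without replicate 2 (open circles). The interferon-stimulated list has medians of 1.64 in CLUSTER, 1.04 in MARRS and 0.48 in MARRS without replicate 2.

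The 2 comparisons with Control shared 1526 genes called higher and 1361 called lower, and 2 genes were called in opposite directions. Independent lists of these sizes would share 326 and 287 genes. Both comparisons use the same Control libraries, and in 20 simulations of unchanged groups with shared controls no gene was called in both. No gene changes in either arm of those simulations, so they could hardly yield shared calls. They do not show how much shared controls raise the overlap of arms with real changes. The log2 fold changes correlated across genes at r = 0.534, within the range of those simulations, which gave 0.488 on average and up to 0.544. Their covariance was 0.612, against 0.245 on average and up to 0.303. Leaving out MARRS replicate 2 gave 1865 genes shared higher, 1739 lower and 432 opposite. The correlation was then r = 0.436 and the covariance 0.774. The simulations kept all 9 libraries and are not matched to that fit.

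The comparison of MARRS with CLUSTER asked how the arms differed from each other, with 3 libraries each. With all libraries, 1 feature was called, an assembled transcript without an annotated gene name, MSTRG.41170.5, which was named for being the only call. It had 89.7 ± 8.23 CPM in CLUSTER, 37.1 ± 1.71 CPM in MARRS and 52.0 ± 5.69 CPM in Control (SD, n = 3 each), and the log2 fold change was -1.27 (SE 0.10, adjusted p = 0.0158). This call ended with the replicate number as a block and when Control replicate 2, Control replicate 3 or MARRS replicate 1 was left out. Named by rule as values only, NEDD8, a ubiquitin-like modifier, had a log2 fold change of -0.73 (adjusted p = 0.0651), and BOK, a BCL2 family gene, and CLIC1, a chloride channel gene, had -0.72 and -0.54 (adjusted p = 0.122 each). MPPED2 and RAB3D, a small GTPase of secretion, had 0.51 and 0.56, and ZSCAN31, a zinc finger gene, was 2.01-fold of the CLUSTER level in MARRS (adjusted p = 0.122 each). At an unadjusted p under 0.05, 4435 features passed in edgeR. DESeq2 called 2507 features and limma-voom 1. Without MARRS replicate 2, edgeR called 5642, of which 2614 were higher and 3028 lower.

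Camera with its preset correlation called 13 lists between the arms, although no list member was called over all features. With an estimated correlation 0 were called (lowest adjusted p = 0.579), and fry called 4 lists, 3 of them among the 13. Cytosolic ribosomal proteins had a downward test in MARRS, with 0 of 61 members called, 53 lower adjusted over the list alone, and a median of -0.28 (camera adjusted p = 3.08e-17, adjusted p = 0.579 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.54 and 23 lower of 28 adjusted over the list alone (camera adjusted p = 9.24e-12, adjusted p = 0.579 with an estimated correlation), with log2 fold changes of -0.70 for ADM and -0.66 for SLC2A1. Interferon-stimulated genes had a median of -0.67 and 0 of 50 adjusted over the list alone (camera adjusted p = 2.18e-09), and NF-kB and inflammatory genes had -0.73 and 4 lower of 25 (camera adjusted p = 6.26e-09). Both had an adjusted p = 0.579 with an estimated correlation, as did G2/M genes, with a median of 0.45 and 23 higher of 27 adjusted over the list alone (camera adjusted p = 9.36e-09). The cholesterol list had a median of -0.69 with 18 lower and 2 higher of 27 adjusted over the list alone (camera adjusted p = 1.62e-08), and G1/S genes had -0.26 with 17 lower of 26 (camera adjusted p = 1.40e-07), both with an adjusted p = 0.579 with an estimated correlation. Fibroblast markers had a median of 0.52 and 7 higher of 11 adjusted over the list alone (camera adjusted p = 0.00106, adjusted p = 0.579 with an estimated correlation), and COL1A1 had a log2 fold change of 1.11 (adjusted p = 0.122). Mitochondrially encoded genes had a median of -0.56 (camera adjusted p = 0.000252), double-stranded RNA sensing genes -0.46 and heat shock genes -0.23 (camera adjusted p = 0.00384 each), all 3 with an adjusted p = 0.579 with an estimated correlation. Transcripts without a poly(A) tail had -0.35 (camera adjusted p = 0.0216) and lysosome genes -0.12 (camera adjusted p = 0.0239), calls that ended without MARRS replicate 1 (adjusted p = 0.0908) or CLUSTER replicate 3 for the former and without MARRS replicate 2 (adjusted p = 0.0649) or CLUSTER replicate 2 for the latter. These 2 lists too had an adjusted p = 0.579 with an estimated correlation.

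Without MARRS replicate 2, 38 of 50 interferon-stimulated genes were lower in MARRS than in CLUSTER and 1 higher, with a median of -1.14. The NF-kB list had 22 lower of 25 and a median of -1.40, and the cholesterol list had 25 lower and 1 higher of 27 and a median of -1.13. All 13 mitochondrially encoded genes and 55 of 61 ribosomal protein genes were lower, and 21 of 27 G2/M genes and 9 of 11 fibroblast markers were higher. Double-stranded RNA sensing genes had 14 lower and 2 higher of 19 and a median of -0.75, heat shock genes 13 lower and 1 higher of 18 and -0.44, and transcripts without a poly(A) tail 9 lower of 14 and -0.68. In that fit fry called 20 of the 25 lists, against 4 with all libraries. Camera called 13 lists there, none of them with an estimated correlation (lowest adjusted p = 0.377). The lysosome list was no longer among them, and p53 targets were added (10 lower and 3 higher of 24, camera adjusted p = 0.0435, adjusted p = 0.494 with an estimated correlation).

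Reads of close relatives limit some of the counts above. HLA and IFITM members of the interferon list and ribosomal protein genes and GAPDH share sequence with relatives or pseudogenes, and how such reads were assigned is not stated.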

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

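The tests of the 3 patterns in this part were chosen after the patterns were seen, those of a wrong label, the cell line, blood cells and a culture condition also after the values they use, and the length and GC trends are a setting added after seeing the data.

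In ADAR, MARRS replicate 2 stood at the CLUSTER level. On the first principal component its score of 22.2 lay between MARRS replicates 1 and 3 (-29.9 and -35.0) and the CLUSTER libraries (39.3 to 90.0). On the second, its score of 0.396 was within the CLUSTER range of -9.29 to 15.5. On the third, this library scored 58.9, outside the CLUSTER range of -82.6 to 41.6. A fit without it called genes between CLUSTER and MARRS replicates 1 and 3, and over 5619 of these its median position was 0.861 on a scale from 0 (MARRS replicates 1 and 3) to 1 (CLUSTER), while CLUSTER libraries, each left out together with MARRS replicate 2 (2 libraries against 2 beside Control), had 0.810, 1.03 and 0.914. A stronger response of the kind seen in MARRS replicates 1 and 3 is argued against by a median position of 0.955 over the 2796 genes in which such a response would lead away from CLUSTER, and a trend on gene length or GC content by a position of 0.880 after its removal. A single wrong label is a candidate explanation consistent with these values, and no CLUSTER library lay near 0 on this scale, so a swap within the deposited CLUSTER and MARRS libraries has no partner. Variation between cultures and a mixed sample stay open and untested. In MSTRG.41170.5 this library, at 36.6 CPM, stood with the other MARRS libraries at 35.7 and 39.0 CPM. That feature was picked as the only call between the arms with all libraries. Such a choice favours agreement within MARRS, so its values do not bear on the label. Among the genes that differed 2-fold or more, 116 of 967 placed this library nearer MARRS replicates 1 and 3. The counts for CLUSTER replicates 1, 2 and 3 were 263 of 1178, 131 of 986 and 150 of 1033.

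The luminal genes ESR1, GATA3 and CDH1, like the other genes of this paragraph chosen after their values were seen, reached at most 0.586 CPM in any of the 9 libraries labelled MCF-7, and 11 of 22 luminal identity genes (50%) but 4 of 23 basal and mesenchymal genes (17.4%) were under 1 CPM on average. AGR2 and AGR3 had 0 CPM in every library. Of the 22 luminal genes, 7 averaged at least 10 CPM, among them KRT8, KRT18, ELF3, MUC1 and TFAP2A at 984, 503, 76.1, 64.3 and 50.2 CPM. VIM, KRT17 and TGFBI averaged 1597, 2240 and 1724 CPM. The low values of ESR1, GATA3 and CDH1 are consistent with cells that are not of the labelled luminal line or have lost part of its luminal expression, which the table does not separate. A loss of reads in counting that was confined to ESR1, GATA3 and CDH1 would not account for the 11 of 22 luminal genes under 1 CPM. Whether reads of more genes were lost stays open. Of the estrogen response list 25% was under 1 CPM, between the shares that would speak for and against it. That share cannot decide the question, since a gene whose reads were lost and a gene that is not expressed both count low. The 7 of 28 genes under 1 CPM included TFF1, GREB1 and PGR at 0.0407, 0.297 and 0.0142 CPM. Another 15 genes of the list averaged at least 10 CPM. The low levels are shared by the 3 groups, so no comparison between groups bears on them.

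Of 50 interferon-stimulated genes, 42 were called higher in CLUSTER and 25 in MARRS (adjusted p = 0.579 with an estimated correlation for both lists). Without MARRS replicate 2 the MARRS median fell from 1.04 to 0.48, with 30 genes called higher and 5 lower. The list stayed called upward by camera in that fit (adjusted p = 1.70e-05, or 0.509 with an estimated correlation). RNA from blood cells is argued against by marker levels, since the highest mean in CLUSTER among PTPRC, CD3E, CD14, LYZ and TYROBP was 0.440 CPM, although CD68, which many cell types express, reached 15.8 CPM. A gene length or GC content trend is argued against as the whole cause of the rise in CLUSTER, since 92.9% of the 42 genes (39) stayed called higher there with offsets for both. The median log2 fold change of the 42 was 1.73 before and 1.82 after. For the genes called higher in MARRS this count was not made. A difference in culture, such as oxygen or density, cannot be told apart from the treatment, because 10 lists outside the interferon and double-stranded RNA lists were called by camera in the same comparison (0 with an estimated correlation, lowest adjusted p = 0.579) and every condition that varied with the group is confounded with it. An effect of the treatment that the groups name stays among the open explanations, as does any difference between the arms in what was delivered, which the labels do not state.

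MSTRG.41170.5 had a log2 fold change of -1.27 between MARRS and CLUSTER (adjusted p = 0.0158), as the only call of the direct test between the arms, and this call ended with the replicate number as a block and without Control replicate 2, Control replicate 3 or MARRS replicate 1.

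The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. Between CLUSTER and Control the real split called 5064 features and the highest other split 1, and between MARRS and Control the real split called 4100 and the highest other 4, so that 1 of 10 splits, the real one, reached the count in each. Between MARRS and CLUSTER the real split called 1 feature, the highest other split 4, and 7 of 10 splits called at least as many as the real one.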

How the results depend on the processing

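The fits without a library of the uncompared group, without assembled transcripts and with length and GC offsets were chosen after seeing the data. Counts of called genes in both comparisons with Control stayed within 1.5 times their value under every other tool, scaling, filter and covariate run, at 4502 to 6237 for CLUSTER (5064) and 3365 to 5413 for MARRS (4100). With the replicate number as a block they were 4502, 3365 and, between MARRS and CLUSTER, 0. Correlations of residuals across groups had a median of 0.019 for equal numbers (-0.016 to 0.032) and -0.004 for unequal ones (-0.041 to 0.015). They do not settle whether the numbers pair the libraries, because the ranges overlap and the MARRS residuals carry the outlying replicate 2. With length and GC offsets, available for 87.1% of the features, 42.0% of the MARRS calls against Control were higher, against 52.7%.

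Leaving out single libraries gave 3143 to 6956 calls for CLUSTER and 1886 to 6421 for MARRS against Control, with 418 to 1111 of 2-fold or more in MARRS. The upper values of each come without MARRS replicate 2 and the lower values without Control replicate 3. Calls shared by both comparisons (2887) ranged from 1482 to 3604. Between MARRS and CLUSTER the calls ranged from 0 to 5642, with 0 to 990 of 2-fold or more, and did not exceed 12 when a library other than MARRS replicate 2 was left out. DESeq2 called 2507 there (307 of 2-fold or more), the fit of only the 6 libraries 3 (3), and the fits with a replicate block, without assembled transcripts and with length and GC offsets 0 (0 of 2-fold or more in each). The single call is an assembled transcript with no length or GC value, so the last 2 fits did not test it, and the cause of the other differences was not tested.

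ADAR ranged from 0.77 to 0.84 in CLUSTER, from -0.067 to 0.46 in MARRS against Control and from -0.87 to -0.34 between the arms when single libraries were left out. The ADAR rise in CLUSTER passed the threshold in every other setting run and missed it without any 1 of the 6 compared libraries, with fewer libraries in the fit. Camera called 38 of the 75 list tests, 0 with an estimated correlation, and fry called 25. Without MARRS replicate 2, the medians against Control turned to -0.11 for the NF-kB list (highest without another library 0.91) and to 0.0165, with a downward test, for the cholesterol list (highest 0.58), and the cause was not tested. Of the 166 calls of named genes, 136 to 166 held in the same direction in each setting. DESeq2 gave no adjusted p for TRIM22 and OAS2 in both arms and for MX2 in CLUSTER, and limma-voom did not call TRIM22 and OAS2 in MARRS (adjusted p = 0.169 and 0.082).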

Other observations

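The genes in this paragraph were chosen after their values were seen. They are single genes that set MARRS replicates 1 and 3 apart from Control or CLUSTER. EGR1, a transcription factor induced within minutes by growth factors, had 6.44 and 6.18 CPM in these libraries, against means of 116 CPM in Control and 92.5 ± 33.1 CPM in CLUSTER, and 150.4 CPM in MARRS replicate 2. FOS, another early transcription factor, had 7.53 and 6.51 CPM against 33.4 in Control, and ASS1, which makes argininosuccinate, 49.8 and 50.7 against 206 CPM. SERPINE1, the inhibitor of plasminogen activators, had 156 and 148 CPM against 21.7 in Control and 58.7 ± 12.3 in CLUSTER, and ITGB3, an integrin subunit, 24.6 and 22.6 against 3.29 and 5.72 CPM. ACTC1, a muscle actin, MFAP5, a microfibril protein, and ID1, a target of BMP signalling, were 4.33-fold, 5.38-fold and 4.83-fold of the CLUSTER level. TRIM22, CCL2, a chemokine that attracts monocytes, and CXCL10, an interferon-induced chemokine, were at 0.0787, 0.117 and 0.0929 of it. In the fit without MARRS replicate 2 (edgeR, n = 2 against 3), the differences of these genes from the groups named had adjusted p of 0.00285 or less, and FOS differed from CLUSTER as well (adjusted p = 0.00723). These p values hold only with that library left out, since its distance from MARRS replicates 1 and 3 does not enter them. The list of immediate early genes, to which EGR1 and FOS belong, went both ways against Control in that fit, with 6 higher and 6 lower of 24.

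Some genes of uncalled lists moved in the same direction in both arms, with MARRS replicate 2 included. PLK2, a kinase and p53 target, rose from 76.0 ± 4.30 CPM in Control to 182 ± 20.1 in CLUSTER and 209 ± 18.4 in MARRS (SD, n = 3 each, adjusted p = 0.000217 and 0.000205). PHLDA3, a p53-induced inhibitor of AKT, rose 2.10-fold and 1.71-fold, while XPC, a DNA damage sensor of the same list, fell to 0.676 and 0.714 of the Control level. RERG, a small GTPase of the estrogen list, rose 1.48-fold and 1.61-fold. KRT8 rose 1.74-fold and 1.56-fold, and HSPB1, a small heat shock protein, 1.48-fold and 1.32-fold. The p53 list as a whole had 7 higher and 4 lower of 24 in CLUSTER and 4 and 4 in MARRS, or 8 and 6 and 4 and 10 without MARRS replicate 2.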
